A study of Homo sapiens with 24 samples.

How the data were processed

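Total RNA of the human prostate cancer cell lines PC-3, DU145 and LNCaP was measured on 24 oligonucleotide arrays with 2 dyes. By the labels, each array carried a docetaxel sample and its time-matched ethanol control. Per the labels, the cells were incubated for 48 h, then grown with docetaxel (PC-3 10 nM, DU145 9 nM, LNCaP 3.5 nM, the half-maximal inhibitory dose of each line) or with 0.005% ethanol and harvested at 8, 24, 48 and 72 h. A harvest at 0 h is also described in the labels and is not analysed here. Control levels of some genes that mark the lines are not reported here. The arrays fall into 12 groups (3 lines at 4 times) of 2 arrays: by the labels, replicate 1 carried docetaxel in Cy5 and replicate 2 carried it in Cy3. Per the labels' protocols, this dye swap was made to have technical replicates. The labels do not say that the replicates are separate cultures, so p-values at single times measure only the spread between these samples, which may be technical.

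The authors deposited scanner output for every array: spot intensity values in both dyes with local background, flags, and a log10 ratio. Per the file headers, the spots were read with Agilent Feature Extraction 10.7.3.1 (the series text names 10.5), whose log10 ratio of Cy5 over Cy3 was background subtracted, detrended and dye normalized. The intensity values used here were the spot means and background medians, deposited without normalization. The authors also deposited a series table of 48 columns of normalized intensity, with a column per sample and dye. Probes are 60 bases long and their positions are given on hg19, as in the files. Each array held 62976 spots, of which 4259 were control spots, and the other 58717 gave 42405 probes. Symbols were brought up to date with a table of reference transcripts (assembly GRCh38.p14, used for names only): 24826 probes were named by accession, 1188 by symbol and 472 by older symbol, and 15919 kept the name in the files, which in many cases is a clone or transcript name.

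Intensities were background corrected (normexp, offset 50) and normalized within each array by loess in limma 3.58.1 (R 4.3.3, statmod 1.5.0), with control spots and outlier spots given weight 0. Ratios were oriented as docetaxel over control by the labels. A probe was kept if it was well above background in either dye on both arrays of at least 1 group, which left 33578 probes. Each gene was read from its brightest probe, which gave 27671 genes tested, 17239 with a symbol and 10432 named only by clone or transcript, and 202 had a missing value.

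Fits and gene lists were written down before the data were examined. For the mean over times, the swap pairs were averaged and the 4 times of a line were treated as replicates, with a spread shared by the 3 lines. Differences between lines used the same fit. For single times and for 72 h minus 8 h, all 24 arrays were fitted with the 12 groups and a dye term per line, which is also the replicate block because replicate number and dye orientation coincide. The spread of this fit was shared by the 12 groups, those of DU145 included, and lines were not fitted alone at single times. SDs given beside values are those of the 2 arrays with the dye part left in, so they are not the spread behind the p-values. The dye parts of the arrays correlated between times in all 6 pairs of times of each line (r 0.497 to 0.638 in PC-3, 0.484 to 0.608 in DU145, 0.174 to 0.528 in LNCaP), so replicate numbers pair the samples through the dye. Moderated tests were those of limma with Benjamini-Hochberg adjustment over all genes, and a gene passed at an adjusted p under 0.05. All tests were 2-sided.

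The 26 gene lists were a list with CDKN1A, MDM2 and BAX (the CDKN1A list), G2 and mitosis, S phase and DNA replication, tubulins, microtubule-associated proteins, NF-kappaB and cytokines, interferon response, a list with KLK3, KLK2 and TMPRSS2 (the KLK3 list), unfolded protein and integrated stress, heat shock, apoptosis regulators, drug transport and taxane metabolism, cholesterol synthesis, EMT and matrix, YAP and SRF targets, immediate early genes, hypoxia and glycolysis, autophagy and lysosome, ribosomal proteins, replication-dependent histones, neuroendocrine, marks of LNCaP, marks of PC-3 and DU145, fibroblast, leukocyte and endothelium. Another list held 3 of the 25 genes of the CDKN1A list, 10 of the 24 genes of the KLK3 list, 7 of the 10 marks of LNCaP and 4 of the 27 apoptosis regulators. Lists were tested against all other genes with camera (preset correlation 0.01), again with a correlation estimated from the data, and with fry; p-values were adjusted over the 156 tests on the mean over times, and over the 260 tests at single times and on the difference of LNCaP and PC-3. The tests at single times were added after the mean over times had been seen, as were tests of LNCaP minus PC-3 at each time. With camera 56 of the 156 and 117 of the 260 passed, and 76 of the 117 also passed with an estimated correlation.

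Genes were named by a rule written before the data were examined: the largest rises and falls per line in the mean over times with 1 sign on all 8 arrays, the members of each list with the smallest p, the largest differences between lines and between 72 and 8 h, genes above background in 1 sample type only, and a fixed set (CDKN1A, MDM2, GDF15, CCNB1, CDC20, PLK1, TUBB, TUBA1B, TUBB3, ABCB1 and KLK3). ABCB1 had no probe that passed the background filter. The same rule was added at single times, for DU145 in the authors' table, and for LNCaP minus PC-3 at 72 h, after the data were seen. List members named as further examples were chosen after their values were seen.

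In the series table, columns were matched to the array channels by correlation (lowest r 0.994). All 16 columns of PC-3 and all 16 of LNCaP matched the channel that the labels give, but 8 of the 16 columns of DU145 matched a channel that the labels give to the other condition. DU145 was therefore analysed by the labels, as planned, and also by the names in the authors' table, each ratio centred on its median; the medians before centring were -0.09, 0.13, -0.15 and 0.05 at 8, 24, 48 and 72 h. In the table, each DU145 ratio compares 2 arrays, so array-to-array error is not in the spread between its replicates, and no single-gene p is given at single times.

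Alternatives were the scanner software's log10 ratios, median centring without loess, no filter or a strict filter on dim probes (17062 probes above background on all arrays), the mean of all probes of a gene, the authors' table, no replicate block, a single dye term for all lines, each line fitted alone, all arrays with the group as a random block, and each array or time left out. Added after the data were seen were the centred table and DU145 from intensity differences between arrays. Also added was a fit without the LNCaP array that had a low share of Cy5 spots above background (the weak array). The slide could not be fitted as a block, since each line was on its own slide.

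The scripts were tested on simulated data in which 100 genes each were changed by known amounts. In the simulated PC-3 fit at 72 h, 89% of genes with a log2 change of 0.5 and 99% of those with 1 were called among 27469 genes, with 10 unchanged genes called. In the simulated mean over times of LNCaP, 98% at a log2 change of 1 were called, and in the simulated difference of LNCaP and PC-3 95% were. Of the lists, the shifted list was found and 1 of 25 others was called. Genes were simulated without correlation between them, so this does not show how often lists are falsely called in the real data. On each array 63.8 to 77.1% of spots were well above background in Cy3 and 48.2 to 77.3% in Cy5, no spot was saturated, and the number of arrays limits the precision.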

Results

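Gene expression was measured in 3 prostate cancer cell lines during 72 h of docetaxel, a taxane that binds and stabilises microtubules. Each line was sampled at 8, 24, 48 and 72 h at its own dose, 10 nM in PC-3, 9 nM in DU145 and 3.5 nM in LNCaP. By the labels, every treated sample was paired on an array with an ethanol control of the same time, while the authors' table names the DU145 channels otherwise. There were 2 arrays in each of the 12 groups, with the dyes exchanged between them. Values are log2 ratios of docetaxel over control, as the mean of 2 arrays with the SD between them unless said otherwise. On single arrays 63.8 to 77.1% of spots lay well above background in Cy3 and 48.2 to 77.3% in Cy5. The question was which genes respond in each line, when, and whether the lines differ.

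The control samples differed in the marks of the lines. KLK3, which encodes prostate-specific antigen, had a log2 intensity of 16.80 (SD 0.08, n = 4 times) in LNCaP and was not above background in any of 8 control channels of PC-3 or DU145. VIM, an intermediate filament gene of mesenchymal cells, was at 16.62 in PC-3, 16.60 in DU145 and 8.06 in LNCaP. For DU145 these are the channels that the labels call control, and by the names in the authors' table some of them hold treated RNA.

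In PC-3 at 24 h genes of G2 and mitosis rose while S phase genes fell. CCNB1 (NM_031966, hg19 chromosome 5, 68473065 to 68473123), the cyclin that drives entry into mitosis, rose by 0.65 (SD 0.05, n = 2, adjusted p = 1.01e-05). CDC20 (NM_001255, hg19 chromosome 1, 43826537 to 43826596), an activator of the anaphase-promoting complex, rose by 0.54 (SD 0.04, n = 2, adjusted p = 0.000297). Of 30 genes of G2 and mitosis 26 rose and 0 fell (27 rose adjusted over the list alone). The list median was 0.45 (adjusted p = 7.02e-44, and 0.0141 with an estimated correlation). Of 30 S phase genes 16 fell and 0 rose (21 fell adjusted over the list alone). Among them were CCNE2, a cyclin of S phase entry, at -0.74 (SD 0.21, n = 2) and UNG, a DNA repair glycosylase, at -0.62 (SD 0.18, n = 2). The S phase median was -0.23 (adjusted p = 1.19e-18, and adjusted p = 0.0651 with an estimated correlation).

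Tubulins, cytokines and histones also rose in PC-3 at 24 h. Of 15 tubulin genes 8 rose and 0 fell (10 rose adjusted over the list alone). The tubulin median was 0.25, above 0 under every scaling (adjusted p = 2.54e-11, and 0.0103 with an estimated correlation). TUBB2A (NM_001069, hg19 chromosome 6, 3154035 to 3154094), a beta tubulin, rose by 0.48 (SD 0.06, n = 2). Of 24 genes of NF-kappaB and cytokines 12 rose and 0 fell (14 and 1 adjusted over the list alone). The secreted factors IL11 at 0.89 (SD 0.07, n = 2), CXCL2 at 0.79 (SD 0.05, n = 2) and IL6 at 0.77 (SD 0.19, n = 2) led this list (adjusted p = 2.27e-15, and 0.0034 with an estimated correlation). Of 12 histone genes 7 rose and 1 fell (8 and 1 adjusted over the list alone), with H2BC4 at 0.71 (SD 0.10, n = 2). The histone median was 0.37, above 0 under every scaling (adjusted p = 0.0141 with an estimated correlation). Interferon response genes went down: 10 of 26 fell and 0 rose (18 fell adjusted over the list alone). Examples were MX1, an antiviral GTPase, at -0.33 (SD 0.39, n = 2) and IFIT2 at -0.28 (SD 0.16, n = 2). The interferon list stood at -0.21 (adjusted p = 1.01e-11, and adjusted p = 0.0507 with an estimated correlation). Without replicate 2 MX1 was at -0.09 (adjusted p = 0.999) and IFIT2 had adjusted p = 0.231, and without the replicate block neither passed (adjusted p = 0.324 and 0.178). With the scanner software's log ratios IL11 and CXCL2 were about as high, at 0.93 and 0.83, and did not pass (adjusted p = 0.144 and 0.0611).

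Smaller shifts at 24 h in PC-3 were upward for immediate early genes (8 of 18 rose, 2 fell), hypoxia and glycolysis (5 of 19 rose), heat shock (2 of 17 rose, 1 fell, median 0.11, above 0 under every scaling) and microtubule-associated proteins (3 of 26 rose, 1 fell). These passed with an estimated correlation (adjusted p = 0.00528, 0.0283, 0.0207 and 0.0416). Counts of the lists adjusted over the list alone differed by at most 8. Marks of PC-3 and DU145 shifted up with the preset correlation (3 of 11 rose, 1 fell, adjusted p = 0.00736) and had adjusted p = 0.215 with an estimated correlation. Single genes that fell included MYB, a transcription factor, at -0.76 (SD 0.09, n = 2), SPARC, a matrix glycoprotein, at -0.76 (SD 0.38, n = 2), and HPGD, which degrades prostaglandins, at -0.88 (SD 0.54, n = 2). With the scanner software's log ratios SPARC and HPGD had falls about as large, at -0.81 and -0.93, and did not pass (adjusted p = 0.0682 and 0.114). Without replicate 2 the fall of HPGD was smaller, at -0.48.

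In total 1433 of 27671 genes passed in PC-3 at 24 h, 568 higher and 865 lower. Across genes the ratios of the 2 arrays at 24 h, with the dye part left in, correlated at only r = 0.065. Without replicate 1 at that time 1125 passed and without replicate 2 92 passed. Without the replicate block 410 passed, with the scanner software's log ratios 690, and under median centring 535. At 8 h 0 genes passed in PC-3 (limma; 965 at an unadjusted p under 0.05), against 43 without replicate 1 and 9 without replicate 2. CDC20 and TUBB2A at 24 h each had adjusted p = 0.0512 without replicate 2. Of the lists at 8 h in PC-3, tubulins stood at 0.12, above 0 under every scaling, with 8 of 15 higher adjusted over the list alone (adjusted p = 7.41e-10, and 0.0123 with an estimated correlation).

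By 48 and 72 h the division genes of PC-3 had turned. CCNB1 fell by 0.69 (SD 0.09, n = 2) and then by 0.91 (SD 0.12, n = 2, adjusted p = 2.84e-09), and CDC20 was at -0.92 (SD 0.03, n = 2) at 72 h. TOP2A (NM_001067, hg19 chromosome 17, 38545709 to 38545768), a topoisomerase of dividing cells, was at -1.39 (SD 0.11, n = 2) and -1.44 (SD 0.12, n = 2, adjusted p = 1.49e-08). All 30 genes of G2 and mitosis fell at 48 h and at 72 h. At 72 h their median was -0.96 (adjusted p = 3.64e-30, and 0.0283 with an estimated correlation). Of 30 S phase genes 29 fell at 48 h and 30 at 72 h. The S phase median was then -1.03 (adjusted p = 3.31e-30, and 0.0266 with an estimated correlation). GINS2, a part of the replicative helicase, fell to -1.67 (SD 0.03, n = 2), CCNE2 to -1.52 (SD 0.15, n = 2), the kinetochore gene SPC25 to -1.62 (SD 0.06, n = 2) and the cohesion gene DSCC1 to -1.57 (SD 0.04, n = 2).

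Stress and inflammatory genes were among the largest rises in PC-3 at 72 h. GDF15 (NM_004864, hg19 chromosome 19, 18499890 to 18499949), a secreted stress cytokine, was at -0.16 at 24 h without passing. It rose by 1.86 (SD 0.21, n = 2) at 48 h and 2.64 (SD 0.31, n = 2, adjusted p = 1.01e-10) at 72 h. ATF3 (NM_001040619, hg19 chromosome 1, 212793856 to 212793915), a stress-induced transcription factor, rose by 2.63 (SD 0.11, n = 2, adjusted p = 7.09e-13) at 72 h. The lowest of its 4 probes was at 0.99. IL6 (NM_000600, hg19 chromosome 7, 22771207 to 22771266) rose by 2.43 (SD 0.18, n = 2, adjusted p = 1.13e-11) at 72 h. All 24 genes of NF-kappaB and cytokines rose at 72 h, and the median was 0.95 (adjusted p = 1.67e-20, and 0.00155 with an estimated correlation). BIRC3, an inhibitor of apoptosis, rose by 2.09 (SD 0.05, n = 2) and CXCL2 by 1.94 (SD 0.16, n = 2).

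Interferon genes of PC-3 rose at the late times: 21 of 26 rose at 48 h and all 26 at 72 h. The interferon median was 1.19 at 72 h (adjusted p = 6.85e-23, and 0.0141 with an estimated correlation). MX1 (NM_002462, hg19 chromosome 21, 42831014 to 42831073) rose by 1.81 (SD 0.12, n = 2, adjusted p = 5.16e-10) and OAS1, an antiviral enzyme, by 1.52 (SD 0.02, n = 2) at 72 h. Of 21 genes of unfolded protein and integrated stress 16 rose (median 0.76, adjusted p = 0.013 with an estimated correlation). Of 18 immediate early genes 16 rose and 1 fell (median 0.73, adjusted p = 0.00108 with an estimated correlation). EGR2 rose by 1.18 (SD 0.05, n = 2) and JUNB by 0.76 (SD 0.08, n = 2).

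Further lists rose in PC-3 at 72 h. Apoptosis regulators (16 of 27 rose, 2 fell, median 0.22) included the BH3-only genes PMAIP1 at 1.43 (SD 0.07, n = 2) and BIK at 0.68 (SD 0.11, n = 2). Genes of EMT and matrix (14 of 23 rose, 2 fell, median 0.35) included the transcription factor SNAI1 at 1.49 (SD 0.21, n = 2) and SPARC at 1.34 (SD 0.04, n = 2). Fibroblast genes (7 of 7 rose, median 0.34) included LUM, a matrix proteoglycan, at 1.47 (SD 0.01, n = 2). Cholesterol synthesis (16 of 24 rose, 2 fell, median 0.23) included the epoxidase gene SQLE at 0.54 (SD 0.01, n = 2). Hypoxia and glycolysis (13 of 19 rose, median 0.41) included the mitophagy gene BNIP3 at 0.80 (SD 0.02, n = 2). Autophagy and lysosome (12 of 19 rose, 2 fell, median 0.30) included the autophagosome gene MAP1LC3B at 0.86 (SD 0.10, n = 2). With an estimated correlation these lists had adjusted p = 0.0159, 0.0123, 0.0243, 0.0416, 0.0266 and 0.0141 in that order. The fibroblast median was 1.18 with the scanner software's log ratios and 1.02 in the authors' table. Under median centring apoptosis regulators, cholesterol synthesis and autophagy and lysosome were at 0.11, 0.15 and 0.18. At 48 and 72 h, counts of the lists in PC-3 adjusted over the list alone differed by at most 3.

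Histone and tubulin genes of PC-3 divided at the late times. H2AC19 (NM_001040874, hg19 chromosome 1, 149814259 to 149814318), a histone gene outside the list, rose by 2.47 (SD 0.15, n = 2) at 48 h. The linker histone H1-2 (NM_005319, hg19 chromosome 6, 26056050 to 26056109) rose by 1.98 (SD 0.11, n = 2) at 72 h, while H3C15 fell to -2.27 (SD 0.03, n = 2) and H4C3 to -1.17 (SD 0.17, n = 2). At 72 h 8 of 12 listed histone genes rose and 3 fell. Their median was 0.88, above 0 under every scaling (adjusted p = 0.000372, and adjusted p = 0.0844 with an estimated correlation). Of 15 tubulins 6 rose and 2 fell. The tubulin median of -0.01 was below 0 under every scaling, and the mean was 0.11 (adjusted p = 0.542). TUBB2A rose by 0.75 (SD 0.01, n = 2) and TUBA1B fell by 0.47 (SD 0.13, n = 2). The 3 probes of TUBB ranged from -0.36 to 0.24.

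Genes of the CDKN1A list showed no joint rise in PC-3 with an estimated correlation. At 72 h 11 of 25 rose and 4 fell (12 and 6 adjusted over the list alone; median 0.13, adjusted p = 0.0489, and adjusted p = 0.515 with an estimated correlation). BBC3, a BH3-only gene, rose by 1.19 (SD 0.02, n = 2) and CDKN1A, the p21 inhibitor of cyclin-dependent kinases, by 0.43 (SD 0.23, n = 2, adjusted p = 0.000749). The apoptosis gene BAX fell by 0.39 (SD 0.13, n = 2) and TP53I3 was at -0.04 (adjusted p = 0.648). MDM2, a ubiquitin ligase gene, was at -0.40 (SD 0.12, n = 2). Its 3 probes ranged from -0.40 to 0.11 and their mean did not pass (adjusted p = 0.117). CDKN1A had adjusted p = 0.122 without replicate 2.

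The remaining lists did not pass in PC-3 at 72 h. They were heat shock (5 of 17 rose, 7 fell, median -0.10, below 0 under every scaling and -0.25 under median centring), microtubule-associated proteins (6 of 26 rose, 10 fell), genes of the KLK3 list (4 of 24 rose, 4 fell; median -0.03, mean 0.01, test downward), drug transport and taxane metabolism (4 of 13 rose, 2 fell) and YAP and SRF targets (8 of 19 rose, 3 fell). Also among them were neuroendocrine (3 of 10 rose), marks of LNCaP (3 of 10 rose, 1 fell), marks of PC-3 and DU145 (5 of 11 rose, 4 fell), leukocyte (4 of 8 rose) and endothelium (4 of 7 rose, 2 fell). Ribosomal proteins (4 of 26 rose, 3 fell) had a median of 0.02, which became -0.17 under median centring and -0.02 with the scanner software's log ratios. Members that rose were MAP7, a microtubule binding gene, at 0.34 (SD 0.14, n = 2), the efflux pump gene ABCC2 at 0.54 (SD 0.10, n = 2), SCG2, a secretogranin, at 1.35 (SD 0.05, n = 2), and CD14, a lipopolysaccharide receptor gene, at 0.95 (SD 0.01, n = 2). Without replicate 2 MAP7 did not pass (adjusted p = 0.164).

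In PC-3 7647 genes passed at 48 h (4371 higher, 3276 lower), and 10350 at 72 h (5967 higher, 4383 lower). Without replicate 1 3435 passed at 48 h and 6271 at 72 h, and without replicate 2 4060 and 5964. Without the replicate block 4807 passed at 48 h and 7278 at 72 h, and under median centring 4942 passed at 48 h. Which direction had more genes at 72 h turned with the scaling, with 4746 higher and 4833 lower by the scanner software's log ratios and 4065 and 4206 under median centring. Under the strict filter on dim probes 3046 were higher and 3091 lower at 48 h. Of the 568 genes higher at 24 h, 288 were also higher and 151 were lower at 72 h. Of the 865 lower at 24 h, 193 were also lower and 359 were higher at 72 h.

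**Figure D1:**
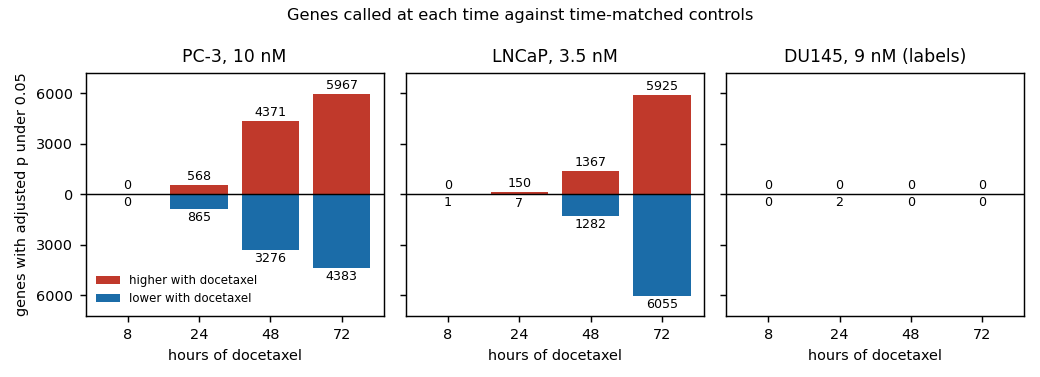
Number of genes with an adjusted p under 0.05 at each time (hours) in PC-3, LNCaP and DU145 as its labels name the channels, drawn apart for genes higher and lower with docetaxel. In PC-3 the counts grew from 0 at 8 h to 10350 at 72 h, and LNCaP at 72 h includes the array with a low share of Cy5 spots above background.

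In LNCaP genes of the CDKN1A list rose from 24 h on. TP53I3 (NM_004881, hg19 chromosome 2, 24300504 to 24300563), an oxidoreductase gene of that list, rose by 1.27 (SD 0.05, n = 2, adjusted p = 4.71e-08) at 24 h and by 2.07 (SD 0.08, n = 2, adjusted p = 1.25e-11) at 72 h. CDKN1A (NM_078467, hg19 chromosome 6, 36652178 to 36652237) rose by 0.97 (SD 0.11, n = 2) and 1.53 (SD 0.10, n = 2, adjusted p = 5.79e-09). The antiproliferative gene BTG2 (NM_006763, hg19 chromosome 1, 203278454 to 203278513) rose by 0.80 (SD 0.06, n = 2) and 1.10 (SD 0.08, n = 2). Of 25 genes of the CDKN1A list 17 rose and 0 fell at 24 h (24 rose adjusted over the list alone; median 0.44). All 25 rose at 48 h (median 0.71) and at 72 h (median 0.89, adjusted p = 3.84e-21). With an estimated correlation the list had adjusted p = 0.00108, 0.00201 and 0.0123 at 24, 48 and 72 h. MDM2 (NM_002392, hg19 chromosome 12, 69238891 to 69238950) rose by 0.75 (SD 0.12, n = 2) at 72 h with probes from 0.32 to 0.75. GDF15 rose by 2.06 (SD 0.30, n = 2) and BBC3 by 1.07 (SD 0.06, n = 2).

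Division genes of LNCaP fell at the late times. All 30 S phase genes fell at 48 h (median -0.63) and at 72 h (median -0.85, adjusted p = 8.95e-25, and 0.0381 with an estimated correlation). MCM4, a helicase gene, was at -1.10 (SD 0.03, n = 2) and MCM6 at -0.60 (SD 0.06, n = 2). DTL (NM_016448, hg19 chromosome 1, 212277852 to 212277911), part of a ubiquitin ligase of replication and outside the list, fell to -1.04 (SD 0.01, n = 2) and -1.17 (SD 0.12, n = 2). Of 30 genes of G2 and mitosis 23 fell at 48 h (29 adjusted over the list alone; median -0.28, adjusted p = 0.0416 with an estimated correlation). At 72 h all 30 fell (median -0.90, adjusted p = 0.0342 with an estimated correlation). UBE2C, a conjugating enzyme of mitotic exit, was at -1.26 (SD 0.05, n = 2) and CCNB1 at -0.98 (SD 0.14, n = 2). At 24 h 1 of 30 genes of G2 and mitosis rose, or 12 adjusted over the list alone (median 0.14, and 0.35 under median centring; adjusted p = 1.1e-12, and adjusted p = 0.133 with an estimated correlation). S phase genes at 24 h gave 0 calls in limma and 10 lower adjusted over the list alone (adjusted p = 4.33e-18, and adjusted p = 0.0693 with an estimated correlation). The median of -0.13 became 0.08 under median centring.

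Tubulins of LNCaP rose early: at 24 h 6 of 15 rose (9 adjusted over the list alone). The tubulin median was 0.18, above 0 under every scaling and 0.42 under median centring (adjusted p = 1.61e-17, and 0.0034 with an estimated correlation). At 72 h 4 rose and 9 fell, with a median of -0.20, below 0 under every scaling and -0.04 under median centring (adjusted p = 0.154). TUBB3 (NM_006086, hg19 chromosome 16, 90002437 to 90002496), a neuronal beta tubulin, rose by 0.43 (SD 0.03, n = 2) at 24 h (adjusted p = 0.113 without replicate 1) and 1.11 (SD 0.02, n = 2) at 72 h. TUBA1B fell by 0.72 (SD 0.25, n = 2) at 72 h. Immediate early genes rose in 5, 9 and 14 of 18 at 24, 48 and 72 h (adjusted p = 0.00108, 0.00108 and 0.00408 with an estimated correlation). At 72 h 1 of them fell, and JUN rose by 1.26 (SD 0.07, n = 2). Apoptosis regulators (18 of 27 rose, 3 fell, median 0.25), autophagy and lysosome (14 of 19 rose, median 0.27) and heat shock (9 of 17 rose, 1 fell, median 0.18, above 0 under every scaling) passed at 72 h with an estimated correlation (adjusted p = 0.0126, 0.0124 and 0.0307). Their medians under median centring were 0.39, 0.46 and 0.33. SQSTM1, an autophagy receptor gene, rose by 1.05 (SD 0.06, n = 2) and the small chaperone gene HSPB8 by 1.26 (n = 2).

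Inflammatory and interferon genes of LNCaP changed in part. Of 24 genes of NF-kappaB and cytokines 10 rose at 48 h (12 adjusted over the list alone; median 0.13, adjusted p = 0.0141 with an estimated correlation). At 72 h 11 rose and 3 fell (adjusted p = 0.00264, and adjusted p = 0.0872 with an estimated correlation), and BIRC3 rose by 1.40 (SD 0.06, n = 2). IL6 and CXCL8 were not above background on any array of LNCaP. Of 26 interferon genes 18 rose and 4 fell at 72 h (median 0.37, adjusted p = 2.52e-06, and adjusted p = 0.152 with an estimated correlation). With the scanner software's log ratios this median was 0.85, and that of NF-kappaB and cytokines at 48 h was 0.22. IFIT2 (NM_001547, hg19 chromosome 10, 91068397 to 91068456) rose by 1.71 (SD 0.14, n = 2) and MX1 fell by 0.22 (SD 0.15, n = 2), a call that ended without the weak array (adjusted p = 0.44). Unfolded protein and integrated stress had 13 of 21 risen and 3 fallen (median 0.28, adjusted p = 0.000967, and adjusted p = 0.113 with an estimated correlation). At 24 h 3 of 19 genes of hypoxia and glycolysis fell (8 fell and 1 rose adjusted over the list alone). LDHA, lactate dehydrogenase A, was at -0.29 (SD 0.14, n = 2) and PDK1, a kinase that limits pyruvate oxidation, at -0.24 (SD 0.06, n = 2). The list's median of -0.10 (adjusted p = 0.0111 with an estimated correlation) turned to 0.08 under median centring. Under median centring LDHA and PDK1 were at -0.05 and -0.02 (adjusted p = 0.697 and 0.836), and without the replicate block neither passed (adjusted p = 0.47 and 0.414).

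Late rises of single genes in LNCaP included VIM at 1.44 (SD 0.01, n = 2) and 2.42 (SD 0.09, n = 2, adjusted p = 1.05e-11) at 48 and 72 h. At 72 h SULF2 (NM_018837, hg19 chromosome 20, 46286424 to 46286483), an extracellular sulfatase, rose by 2.03 (SD 0.06, n = 2), ANGPT2, an angiopoietin, by 2.11 (SD 0.11, n = 2), and UGT2B7, a steroid-conjugating gene of a family with near-identical members, by 2.22 (SD 0.14, n = 2). Genes of the KLK3 list (8 of 24 rose, 9 fell) had a median of -0.01 and a mean of 0.02 at 72 h, and a median of 0.17 under median centring (adjusted p = 0.941). KLK3 was at 0.26 (SD 0.11, n = 2) with probes from -0.24 to 0.26 (adjusted p = 0.124 without the weak array). At 24 h genes of the KLK3 list were at -0.07 and marks of LNCaP at -0.10. They had 4 and 2 members lower adjusted over the list alone and 0 over all genes (limma; adjusted p = 0.0122 and 0.0185 with an estimated correlation). Under median centring these medians were 0.15 and 0.14.

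Other lists did not pass in LNCaP at 72 h, apart from marks of PC-3 and DU145 (6 of 11 rose, 2 fell), which had adjusted p = 0.0323, and adjusted p = 0.324 with an estimated correlation. The phospholipid-binding gene ANXA1 of that list rose by 1.27 (SD 0.14, n = 2). Those not passing were hypoxia and glycolysis (11 of 19 rose, 3 fell), cholesterol synthesis (7 of 24 rose, 10 fell; median 0.04, mean -0.01), EMT and matrix (6 of 23 rose, 3 fell) and YAP and SRF targets (7 of 19 rose, 5 fell). They also included microtubule-associated proteins (5 of 26 rose, 6 fell; median 0.06, mean -0.05), drug transport and taxane metabolism (2 of 13 rose, 1 fell; median -0.02, test upward), neuroendocrine (2 of 10 rose), marks of LNCaP (6 of 10 rose, 2 fell), fibroblast (1 of 7 rose), leukocyte (3 of 8 rose, 1 fell) and endothelium (1 of 7 rose). Ribosomal proteins (6 of 26 rose, 5 fell) had a median of 0.08, above 0 under every scaling. Histones (5 of 12 rose, 5 fell) had a median of 0.06, above 0 under every scaling, with a mean of -0.21. Under median centring ribosomal proteins, histones, cholesterol synthesis and microtubule-associated proteins were at 0.25, 0.24, 0.12 and 0.18. Counts of the lists in LNCaP adjusted over the list alone differed by at most 11 at 24 h, 6 at 48 h and 1 at 72 h.

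In LNCaP 1 gene passed at 8 h, 157 at 24 h (150 higher, 7 lower), 2649 at 48 h (1367 higher, 1282 lower) and 11980 at 72 h (5925 higher, 6055 lower). The gene at 8 h was FHL2, a LIM domain gene, at -0.50 (adjusted p = 0.0331), named after its value was seen. Its call ended without the replicate block, under median centring and with the mean of all probes, which gave 0 genes each. It also ended without replicate 1 and under the strict filter, which gave no lower gene. Under median centring the split at 24 h was 1921 higher and 473 lower, and with the authors' values it was 297 higher and 151 lower. The balance turned at the late times, to 593 higher and 658 lower at 48 h and 6461 and 4215 at 72 h under median centring, and to 5853 and 5124 at 72 h with the scanner software's log ratios. At 72 h the authors' values gave 4742 and 4455, and at 48 h the strict filter gave 1092 and 1415. Without replicate 1 and without replicate 2, 27 and 56 genes passed at 24 h, 973 and 744 at 48 h, and 1 and 39 at 8 h. Without the replicate block 60 passed at 24 h, 1152 at 48 h and 8042 at 72 h. Across genes the ratios of the 2 arrays, with the dye part left in, correlated at r = -0.246 at 8 h and -0.118 at 24 h.

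In replicate 2 of LNCaP at 72 h the median raw Cy5 intensity was not low, at 289.4 against 141.5 to 160.7 on the other arrays of the line. Only 48.2% of its spots were above background in Cy5. It is called the weak array for that share alone, whose cause was not tested. Without it 4399 genes passed at 72 h (2393 higher, 2006 lower), of which 4118 also passed in the same direction with both arrays, and without replicate 1 13126 passed. All 25 genes of the CDKN1A list still rose, and all 30 genes of G2 and mitosis and all 30 of S phase still fell. In that fit 15 interferon genes rose, as did 13 apoptosis regulators, 12 immediate early genes, 7 genes of autophagy and lysosome, 4 of heat shock and 3 marks of PC-3 and DU145. Of unfolded protein and integrated stress 8 rose and 2 fell, with a median of 0.12, and the heat shock median was 0.11. No gene of the interferon list or of NF-kappaB and cytokines fell. Ribosomal proteins (1 rose, 1 fell) were at 0.03, microtubule-associated proteins (2 rose, 4 fell) at 0.03 and histones (3 rose, 2 fell) at 0.10. Cholesterol synthesis (3 rose, 5 fell) turned to -0.07, the KLK3 list (3 rose, 5 fell) was at -0.07, and drug transport and taxane metabolism (1 rose, 1 fell) turned above 0. Of hypoxia and glycolysis 5 rose and 2 fell, of marks of LNCaP 2 and 1, of YAP and SRF targets 3 and 4, and of EMT and matrix 4 and 0.

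**Figure D2:**
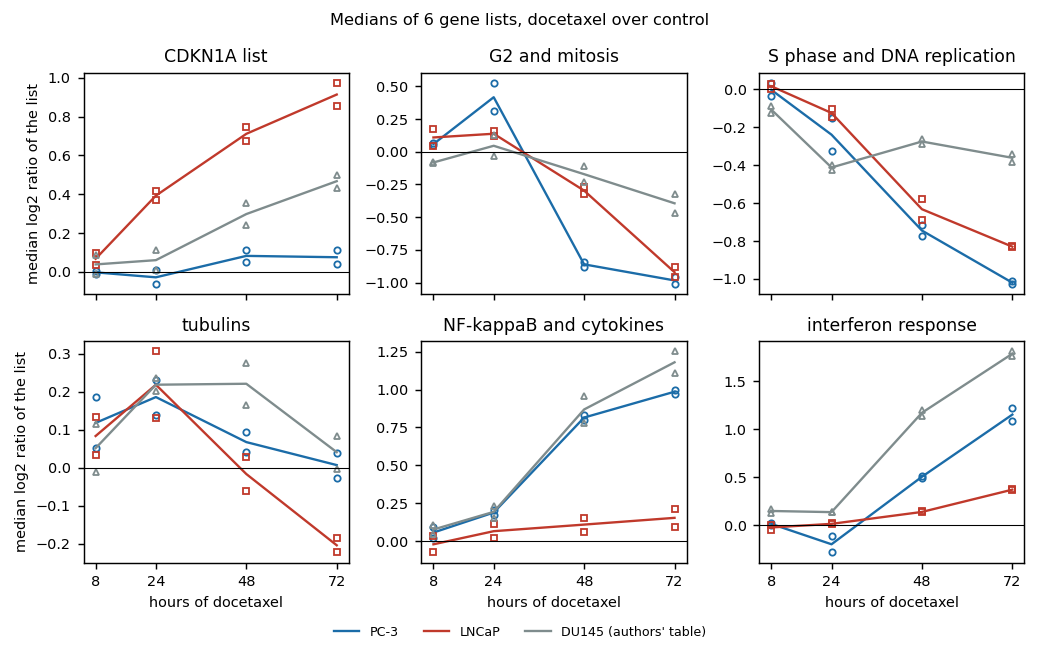
Median log2 ratio of 6 gene lists against hours of docetaxel, where points are single arrays (for DU145, pairs of columns of the authors' table) and lines join their means. DU145 was normalized otherwise than PC-3 and LNCaP, so sizes are not compared between them. At 72 h the arrays gave the CDKN1A list at 0.86 and 0.97 in LNCaP and at 0.04 and 0.11 in PC-3.

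The change between 8 and 72 h was tested within each line. In PC-3 the largest rises of the ratio were GDF15 at 2.45 (SE 0.14, n = 2, adjusted p = 2.54e-08), ATF3 at 2.45 (SE 0.08, n = 2, adjusted p = 2.75e-10), the cytokine IL24 at 2.34 (SE 0.07, n = 2, adjusted p = 1.1e-10) and the ubiquitin ligase NEURL3 at 2.25 (SE 0.09, n = 2, adjusted p = 8.34e-10). The protease gene FAM111B fell to -1.71 (SE 0.12, n = 2, adjusted p = 1.48e-07). In LNCaP they were VIM at 2.55 (SE 0.09, n = 2, adjusted p = 1.08e-09), UGT2B7 at 2.28 (SE 0.09, n = 2, adjusted p = 1.14e-09), ANGPT2 at 2.27 (SE 0.08, n = 2, adjusted p = 1.11e-09) and DIO3, a deiodinase, at 2.59 (SE 0.12, n = 2, adjusted p = 6.1e-09), whose other probe was at 0.84 at 72 h. In PC-3 7176 genes differed (4326 higher at 72 h, 2850 lower) and in LNCaP 8854 (4463 higher, 4391 lower). Under median centring these were 2527 and 2412 in PC-3 and 4980 and 2440 in LNCaP. With the strict filter on dim probes LNCaP had 3399 higher and 4129 lower. In PC-3 4382 passed without replicate 1 and 4952 without replicate 2 at 8 h, and 4733 and 4536 at 72 h. In LNCaP these counts were 5745 and 4970 at 8 h, and 11743 and 4090 at 72 h. Without the replicate block 4336 passed in PC-3 and 4653 in LNCaP. In DU145, read by the labels, 0 passed (limma; 3195 at an unadjusted p under 0.05).

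The dye swaps of DU145 did not mirror each other when read by the labels. CDKN1A was at 0.09 (SE 0.16, n = 4, adjusted p = 1) and GDF15 at 0.08 (SE 0.40, n = 4, adjusted p = 1) in the mean over times. Across genes the ratios of the 2 arrays at 72 h correlated at r = -0.241 in DU145, against 0.815 in PC-3 and 0.518 in LNCaP. Genes are not independent replicates here. At 48 h these were -0.339, 0.711 and 0.37. Earlier, swaps of the other lines did not mirror either: r was -0.298 in PC-3 and -0.246 in LNCaP at 8 h. At 24 h it was 0.065 and -0.118, so DU145 stood apart at 48 and 72 h only. The dye part was left in these ratios, while the fits of single times take it out. By the labels 0, 2, 0 and 0 genes passed at 8, 24, 48 and 72 h (limma; 1798, 1650, 1007 and 1858 at an unadjusted p under 0.05). The 2 at 24 h were lower and had no symbol. Without replicate 1 and without replicate 2, 2 and 57 passed at 8 h, 20 and 90 at 24 h, 0 and 3 at 48 h, and 2 and 12 at 72 h. Ribosomal proteins were the only list to pass on the mean over times by the labels (adjusted p = 0.0415, and adjusted p = 0.562 with an estimated correlation).

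By the column names of the authors' table, single genes of DU145 passed on the mean over times. UBD (NM_006398, hg19 chromosome 6, 29523477 to 29523536), a ubiquitin-like gene induced by cytokines, was at 0.64, 1.80 and 2.71 at 8, 24 and 72 h, and its pairs of columns at 48 h were higher, at 3.08 and 3.11. It rose by 2.06 (SE 0.36, n = 4, adjusted p = 0.0322) over the 4 times. CHGA (NM_001275, hg19 chromosome 14, 93401545 to 93401604), a granin of neuroendocrine cells, rose by 1.75 (SE 0.33, n = 4, adjusted p = 0.0421) and the acute phase gene SAA1 by 1.53 (SE 0.33, n = 4, adjusted p = 0.0499). The BH3-only gene BMF rose by 1.25 (SE 0.24, n = 4, adjusted p = 0.0396) and the alpha tubulin TUBA4A by 0.52 (SE 0.11, n = 4, adjusted p = 0.0472). IMPACT, a regulator of translation, fell by 0.52 (SE 0.09, n = 4, adjusted p = 0.0261) and TPM1, a tropomyosin, by 0.47 (SE 0.10, n = 4, adjusted p = 0.0472). Means that did not pass were ATF3 at 1.73 (adjusted p = 0.0964), OAS1 at 1.63 (adjusted p = 0.0746), GDF15 at 1.49 (adjusted p = 0.101), IFITM1 at 1.34 (adjusted p = 0.0613) and CDKN1A at 0.89 (adjusted p = 0.091). In all 366 genes passed after centring (302 higher, 64 lower) and 144 as deposited (125 higher, 19 lower).

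Interferon genes led the lists of DU145 in the authors' table, with a median of 0.83 (0 of 26 over all genes in limma, 17 higher adjusted over the list alone; adjusted p = 8.59e-09). NF-kappaB and cytokines had 1 of 24 risen, 12 adjusted over the list alone (median 0.57, adjusted p = 1.76e-05). Immediate early genes had 1 of 18, 12 adjusted over the list alone (median 0.59, adjusted p = 9.84e-07). The S phase list was at -0.28 (adjusted p = 0.00043) and the CDKN1A list at 0.26 (adjusted p = 0.0032). Each of these lists had adjusted p = 0.786 with an estimated correlation. Lists of other cell types also stood above 0 in these columns. At 72 h endothelium was at 0.754 (7 of 7 genes above 0), leukocyte at 0.511 (7 of 8) and fibroblast at 0.439 (7 of 7), against 1.775 for interferon. At 24 h fibroblast was at 0.552 and endothelium at 0.477, above interferon at 0.125. Each of these ratios compares 2 arrays, and the cause of these rises was not tested. The table is also normalized otherwise than the values of PC-3 and LNCaP. In PC-3 at 72 h 3573 genes passed with over 1.5-fold in the centred table, against 1636 in the main fit. How far this sets the sizes in DU145 was not tested, so they are not compared with those of the other lines. Labels and table name the DU145 channels differently, so every direction in DU145 belongs to the reading it is given for.

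Averaged over the 4 times, few genes passed in PC-3 and LNCaP. In PC-3 TUBB2A rose by 0.53 (SE 0.07, n = 4, adjusted p = 0.0272) and the growth factor gene TGFB2 by 0.36 (SE 0.05, n = 4, adjusted p = 0.0272). The mucin-like gene DMBT1 rose by 0.36 (SE 0.05, n = 4, adjusted p = 0.0272) and DAW1, a gene of cilia, by 0.38 (SE 0.04, n = 4, adjusted p = 0.0181). In LNCaP BTG2 rose by 0.82 (SE 0.11, n = 4, adjusted p = 0.0273) and CDKN1A by 1.04 (SE 0.16, n = 4, adjusted p = 0.0486). The stress kinase gene PLK3 rose by 0.37 (SE 0.05, n = 4, adjusted p = 0.0486) and the lipase gene CEL by 0.52 (SE 0.06, n = 4, adjusted p = 0.0273), and ACTA2, smooth muscle actin, fell by 0.39 (SE 0.06, n = 4, adjusted p = 0.0486). CATSPERB, a sperm ion channel gene, was above background in every docetaxel channel of LNCaP and in no control channel, and was at least 1.20-fold higher at 48 h. It was named for that pattern, which held at 8 h as well. The log2 ratio at 72 h was only 0.15, and the probe had no mapped position. In PC-3 7 genes passed (6 higher, 1 lower; 5528 at an unadjusted p under 0.05), in LNCaP 24 (23 higher, 1 lower; 2877), and in DU145 by the labels 0 (limma; 232).

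Those counts rested on which times were used and on the spread shared with DU145 read by the labels. With DU145 from intensity differences, or with each line fitted alone on fewer samples, 0 passed in PC-3 and 0 in LNCaP. In PC-3 0 also passed with the scanner software's log ratios and under median centring, where LNCaP had 24 and 38. For TUBB2A and the other genes of PC-3, 2646 genes passed without 8 h, 2 without 24 h, and 0 without 48 h or without 72 h. In LNCaP 258 passed without 8 h and 0 without any of the others. With all arrays, the group as a random block and the replicate block, 2571 passed in PC-3 (1662 higher, 909 lower) and 289 in LNCaP. Genes of the CDKN1A list rose in LNCaP (4 of 25 over all genes, 25 adjusted over the list alone; median 0.51, adjusted p = 1.01e-33). In PC-3 S phase genes were at -0.50 (0 over all genes in limma, 29 lower adjusted over the list alone; adjusted p = 4.04e-17). NF-kappaB and cytokines were at 0.48 (0 over all genes, 21 higher adjusted over the list alone; adjusted p = 1.49e-17). With an estimated correlation these lists had adjusted p = 0.542, 0.542 and 0.542.

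LNCaP and PC-3 were compared at each time in a test added after the data were seen. Genes of the CDKN1A list rose more in LNCaP: at 72 h the difference was 2.11 (SE 0.08, n = 2, adjusted p = 1.5e-09) for TP53I3, 1.16 (SE 0.10, n = 2, adjusted p = 1.16e-06) for MDM2 and 1.10 (SE 0.12, n = 2, adjusted p = 1.06e-05) for CDKN1A. The 3 probes of MDM2 ranged from -0.40 to 0.11 in PC-3 and from 0.32 to 0.75 in LNCaP. The probe used was the lowest in PC-3 and the highest in LNCaP, so no other probe gave a larger difference. In all 19 of 25 were higher and 2 lower (median 0.73, adjusted p = 0.0381 with an estimated correlation). Already at 24 h TP53I3 differed by 1.36 (SE 0.08, n = 2, adjusted p = 2.31e-06) and SULF2 by 1.27 (SE 0.13, n = 2, adjusted p = 0.000484). Single genes with a larger rise in PC-3 at 72 h were MX1, which differed by -2.03 (SE 0.12, n = 2, adjusted p = 2.85e-08), SNAI1 by -1.95 (SE 0.15, n = 2, adjusted p = 4.22e-07) and H1-2 by -1.91 (SE 0.09, n = 2, adjusted p = 4.55e-09). In LNCaP 19 of 24 genes of NF-kappaB and cytokines were lower and 1 higher (median -0.77, and -0.48 with the scanner software's log ratios; adjusted p = 0.00528 with an estimated correlation). Members such as IL6 and CXCL8 were below background in LNCaP, so their differences rest on PC-3 alone. Of 26 interferon genes 20 were lower and 2 higher in LNCaP (median -0.85, adjusted p = 1.52e-09, and adjusted p = 0.0762 with an estimated correlation). At 48 h 29 of 30 genes of G2 and mitosis were higher in LNCaP (median 0.54, adjusted p = 0.0283 with an estimated correlation), CDC20 by 0.67 (SE 0.09, n = 2, adjusted p = 0.000217). At 72 h 6 were higher and 1 lower (median 0.05, adjusted p = 0.137), and under median centring the median was 0.36, with 28 of 30 members above 0.

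Averaged over times, with DU145 read by the labels, no gene passed between LNCaP and PC-3, between LNCaP and DU145 or between PC-3 and DU145 (0 in each, limma; 2673, 1269 and 2433 at an unadjusted p under 0.05). In the authors' table, centred, 3, 11 and 0 passed. With the group as a random block and the replicate block, by the labels, 124, 6 and 0 did. Without 8 h of PC-3 156 genes differed between LNCaP and PC-3 and 203 between PC-3 and DU145. Without 8 h of LNCaP 76 differed between LNCaP and PC-3 and 65 between LNCaP and DU145. At single times LNCaP and PC-3 differed in 0 genes at 8 h (limma; 884 at an unadjusted p under 0.05), 219 at 24 h (145 higher, 74 lower in LNCaP), 3399 at 48 h (1375 higher, 2024 lower) and 9407 at 72 h (4169 higher, 5238 lower). At 72 h the balance turned to 4306 higher and 3345 lower with the scanner software's log ratios and 5934 and 3486 under median centring. Without the weak array 5131 differed at 72 h, and without the replicate block 1492 at 48 h and 5291 at 72 h. Dose, growth medium and slide changed with the line and cannot be told apart from it.

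**Figure D3:**
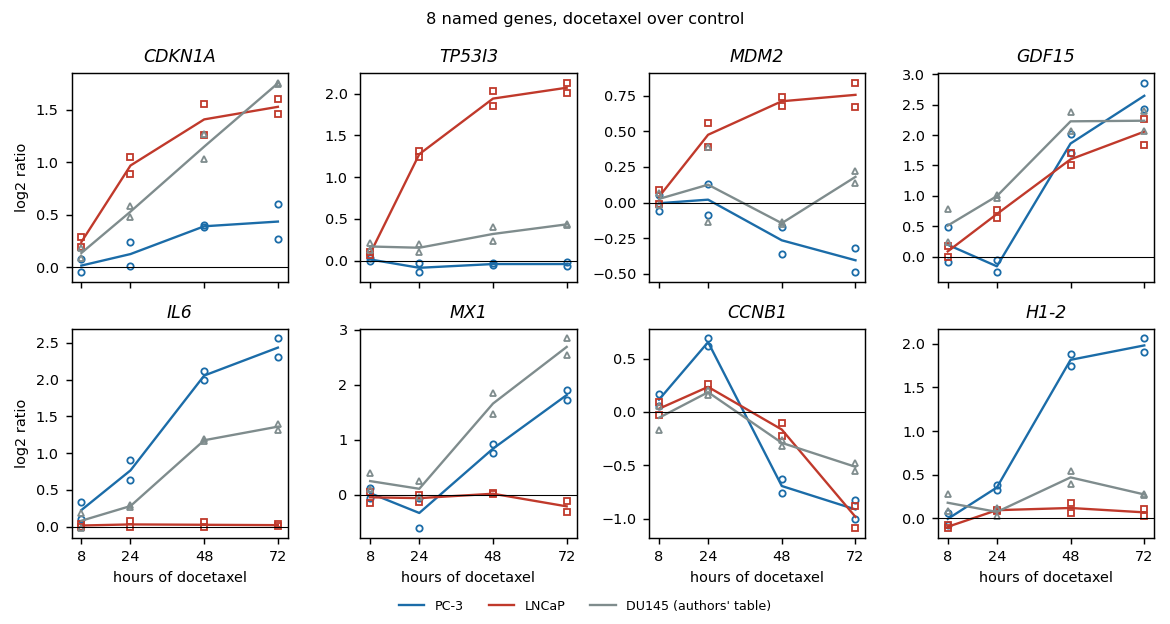
Log2 ratio of docetaxel over control for 8 genes against hours of docetaxel, where points are single arrays (for DU145, pairs of columns of the authors' table) and lines join their means. DU145 was normalized otherwise than PC-3 and LNCaP, so sizes are not compared between them. At 72 h TP53I3 stood at 2.07 in LNCaP and -0.04 in PC-3, and IL6 at 2.43 in PC-3.

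Genes called in PC-3 and in LNCaP overlapped at the late times. GDF15, ATF3, BIRC3 and NEURL3 rose in both lines at 72 h, with GDF15 differing by -0.59 (SE 0.14, n = 2, adjusted p = 0.00568) between LNCaP and PC-3. At 72 h 2521 genes were higher in both lines, where independent lists would share 1277.7, and 1847 were lower in both, against 959.1. Of the rest 618 that were higher in PC-3 were lower in LNCaP and 542 the reverse. These counts rest in part on the weak array of LNCaP. Without it 1454 were higher in both (against 554), 1231 were lower in both (against 361.5), and 149 and 148 went opposite ways. At 48 h 764 and 745 were shared, against 215.9 and 151.8. Across genes the mean responses of LNCaP and PC-3 correlated at r = 0.432 (0.249 under median centring). PC-3 and DU145 correlated at r = -0.017 by the labels and 0.48 in the authors' table, and LNCaP and DU145 at -0.036 and 0.217.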

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

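The tests of LNCaP minus PC-3 at single times were chosen only after the mean over times was seen, as were the tests without the weak array. A test of the difference between lines or between times flagged the following results. LNCaP and PC-3 differed in 219 genes at 24 h, 3399 at 48 h and 9407 at 72 h, and the response at 72 h differed from that at 8 h in 7176 genes in PC-3 and 8854 in LNCaP. Among the lists at 72 h, the median difference of LNCaP minus PC-3 was 0.73 for the CDKN1A list, -0.77 for NF-kappaB and cytokines, -0.26 for cholesterol synthesis, -0.35 for immediate early genes, -0.74 for replication-dependent histones and -0.42 for fibroblast genes, all in the main normalization. Under median centring cholesterol synthesis was at -0.02, immediate early genes at -0.22 and histones at -0.43. With the scanner software's log ratios NF-kappaB and cytokines were at -0.48, immediate early genes at -0.17 and fibroblast genes at -1.27.

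A sample far from the others was replicate 2 of LNCaP at 72 h, where 48.2% of spots were above background in Cy5, the dye of the control, against 66.9 to 69.3% on the other 7 arrays of the line; chance flags about 1 in 20 groups. LNCaP had 11980 genes past the threshold at 72 h against 2649 at 48 h, a step that this array might have made. Without it 4399 passed at 72 h and 3352 at 48 h in the same fit, which leaves open how much of the step it made. With the scanner software's log ratios 1928 passed at 48 h and 10977 at 72 h, and under median centring 1251 and 10676. Both argue against loess in particular as the source of the step. Both also normalize within arrays and keep the weak array, so they cannot decide on such normalization in general. With each time read from 1 array in the same fit, 72 h from replicate 1 had at least 3.57 times the count of 48 h, so a larger response at 72 h than at 48 h did not rest on the weak array alone; a longer exposure stays open as a biological explanation.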

How the results depend on the processing

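The tests with the authors' table centred, without the weak array and with DU145 from intensities were chosen only after the data were seen. Across counts and correlations 181 values stayed the same and 124 moved by more than 1.5 times or the spread, and of the named genes' values 1003 stayed the same, 47 lost the threshold in the same direction and 1 reversed; where no reason is given, the cause was not tested. The reversed one was KLK3 in LNCaP at 72 h, at -0.24 under the strict filter, which leaves another probe. A lone array was assumed to vary like the other groups. The slide as a random block was not run, since each line was on its own slide. Signal over background limits the reading of LNCaP at 72 h. Counts below are of genes, in limma.

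With no replicate block, PC-3 gave 410 at 24 h, 4807 at 48 h and 4336 for 72 h minus 8 h, LNCaP 0, 60 and 1152 at 8, 24 and 48 h and 4653 for 72 h minus 8 h, and LNCaP minus PC-3 1492 at 48 h and 5291 at 72 h. Among named genes, MX1 and IFIT2 in PC-3 at 24 h, LDHA and PDK1 in LNCaP at 24 h and MX1 in LNCaP at 72 h lost the threshold, as did FHL2 in LNCaP at 8 h. With all arrays, the group as a random block and the replicate block, the mean over times gave 2571 in PC-3, 289 in LNCaP, 124 for LNCaP minus PC-3 and 6 for LNCaP minus DU145. Each line fitted alone, which leaves fewer samples for the spread and takes DU145 out of it, gave 0 in PC-3 and 0 in LNCaP.

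With the Feature Extraction log ratio, PC-3 gave 11 at 8 h, 690 at 24 h and 0 over times, DU145 0 at 24 h, 7 at 72 h, 4 for 72 h minus 8 h and 1 over times, LNCaP 10 at 8 h, LNCaP minus PC-3 1 over times and 1979 at 48 h, and LNCaP minus DU145 1. Median centring gave 535 and 4942 in PC-3 at 24 and 48 h and 0 over times, 0, 2394 and 1251 in LNCaP at 8, 24 and 48 h and 38 over times, 1393 for LNCaP minus PC-3 at 48 h, and correlations of 0.249 for LNCaP with PC-3 and -0.089 for PC-3 with DU145. Without a filter on dim probes LNCaP gave 8 over times. The strict filter, with fewer genes tested, gave 0 in DU145 at 24 h, 3 in LNCaP at 8 h, and over times 3 in PC-3, 4 in LNCaP and 1 for LNCaP minus PC-3. The mean of all probes gave 0 in LNCaP at 8 h.

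The authors' table gave 30 and 951 in PC-3 at 8 and 24 h, 3016, 5826, 11742 and 11518 in DU145 at 8, 24, 48 and 72 h and 9302 for 72 h minus 8 h, 127 and 448 in LNCaP at 8 and 24 h, and over times 0 in PC-3, 144 in DU145, 13 in LNCaP, 2 for LNCaP minus PC-3 and 9 for LNCaP minus DU145, with correlations of 0.217 for LNCaP with DU145 and 0.48 for PC-3 with DU145. Centred, it gave 30 and 935 in PC-3, 1350, 4856, 8548, 11739 and 9174 in DU145, 128 and 430 in LNCaP, and over times 0 in PC-3, 366 in DU145, 3 for LNCaP minus PC-3 and 11 for LNCaP minus DU145. The single-time counts of DU145 in the table leave array-to-array error out of the spread. With DU145 from intensities, the mean over times gave 783 in DU145, 0 in PC-3 and 0 in LNCaP, which share its spread.

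With the weak array left out LNCaP gave 36 at 8 h, 4399 at 72 h, 4090 for 72 h minus 8 h and 43 over times, and LNCaP minus PC-3 1 over times and 5131 at 72 h. Of the 156 list tests, 56 passed with the preset correlation, 0 with an estimated one and 0 with fry. Leaving out 1 time, the mean over times ranged from 0 to 2646 in PC-3, 0 to 258 in LNCaP, 0 to 156 for LNCaP minus PC-3, 0 to 203 for PC-3 minus DU145 and 0 to 65 for LNCaP minus DU145, and was 0 in DU145. Leaving out 1 replicate, PC-3 ranged from 9 to 43, 92 to 1125, 3435 to 4060 and 5964 to 6271 at 8, 24, 48 and 72 h and 4382 to 4952 for 72 h minus 8 h, DU145 from 2 to 57, 20 to 90, 0 to 3, 2 to 12 and 0 to 8, and LNCaP from 1 to 39, 27 to 56, 744 to 973, 4399 to 13126 and 4090 to 11743.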

Other observations

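Of the tests in this part, those of the general rise of cell cycle genes, of DU145 and of LNCaP in the G2 and mitosis pattern were chosen only after the result was seen, as was the reading of DU145 by intensity differences. Several genes of the naming rule add to the lists. In LNCaP at 72 h STMN4, a stathmin that destabilises microtubules, rose by 1.90 (SD 0.35, n = 2), SERPINB5, the maspin gene, by 1.59 (SD 0.08, n = 2) and HSPA4L, a chaperone, by 0.95 (SD 0.06, n = 2), and the transcription factor E2F2 fell by 1.13 (SD 0.07, n = 2). In PC-3 at 72 h NDRG1, a stress-responsive gene, rose by 1.23 (SD 0.11, n = 2) and NANOS1, a regulator of translation, fell by 1.10 (SD 0.22, n = 2), and NANOS1 differed by 1.70 (SE 0.10, n = 2, adjusted p = 4.1e-08) between LNCaP and PC-3.

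List differences between LNCaP and PC-3 at 72 h extended beyond the lists of the report. Of 24 genes of cholesterol synthesis 12 were lower and 0 higher in LNCaP (adjusted p = 0.0308 with an estimated correlation), and the same held for 7 of 7 fibroblast genes (adjusted p = 0.0248), LUM by -1.27 (SE 0.07, n = 2, adjusted p = 2.72e-08). Immediate early genes had 10 lower and 3 higher (median -0.35, adjusted p = 0.0307). With the scanner software's log ratios that median was -0.17, and the list stood at 1.01 in LNCaP and 0.93 in PC-3. Under median centring the median difference of cholesterol synthesis was -0.02. Without the weak array 11 genes of cholesterol synthesis, 5 fibroblast genes and 9 immediate early genes were lower.

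The swaps of DU145 did not mirror each other by the labels, unlike those of PC-3 and LNCaP at 48 and 72 h. The authors' table names 8 of the 16 DU145 columns for the other condition. If the table were right, an intensity difference between the 2 arrays would carry the response, and its correlation with the response of PC-3 was at least 0.451 at 48 and 72 h, which goes with channels named otherwise in the labels than in the table. These differences correlated at 0.701 between 48 and 72 h, which goes with a response in DU145. It cannot exclude a lack of one. Replicates 1 and 2 were placed on the same 2 sides of 1 slide at every time, and a fixed difference between the sides would correlate too. A position effect shared by the slides was argued against by the correlation of the difference with those of PC-3 and LNCaP, at most 0.053. An effect of position on the DU145 slide alone was not tested. The names given to the DU145 scanner output also pair control with control and treated with treated, unlike the labels. A naming error in the labels may therefore account for the swaps, as a hypothesis, and only the people who made the arrays could settle it.

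Genes of G2 and mitosis rose at 24 h in PC-3 before they fell. Dye bias was argued against by the lower of the 2 arrays' medians, 0.31, and a general rise of cell cycle genes by the S phase median of -0.232. In DU145 in the authors' table the list median was 0.009 after centring on the median of all genes, with 16 of 30 members above 0. The list thus did not stand apart from other genes in these columns. Before centring the median of all genes at 24 h was 0.133, so whether the list rose together with other genes in DU145 depends on the centring. In LNCaP 12 genes were higher adjusted over the list alone, with medians of 0.156 and 0.119 on its arrays. At 8 h the LNCaP medians were already 0.046 and 0.172, so 24 h did not clearly exceed 8 h. An arrest in mitosis, the known action of taxanes, may give such a pattern, but no count of cells by phase was analysed here, so this stays a hypothesis.

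For the mean over times, other splits of the 8 averaged ratios were counted for each pair of lines, where the real splits gave 0 genes (limma). Every split gives at least 0, so 35 of 35 for LNCaP and PC-3, 35 of 35 for LNCaP and DU145 and 35 of 35 for PC-3 and DU145 were fixed beforehand, and these counts decide nothing about chance. For LNCaP and PC-3 the highest other split called 3705 genes, with 8 and 24 h of both lines against 48 and 72 h, which points to time as a structure of the samples; for the other pairs the highest was 0.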
